A study of Mus musculus with 5 samples.

How the data were processed

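Cells of mouse dorsal root ganglia were measured by droplet single-cell RNA sequencing in 5 libraries, 1 for each group. Per the labels, the mice were 6 to 8 weeks old and of the TRPV1-ChR2-eYFP genotype, ganglia were dissociated with collagenase and dispase, and the cell type was neurons with glia. The series design states that back-skin nociceptors were stained with DiI and sorted by flow cytometry. Gates, numbers of mice per library and sequencing dates are not given in the sources used here.

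The deposited matrices held raw UMI counts per gene and barcode for all barcodes, empty droplets included. Per the file headers they were written by Cell Ranger 4. The processing notes in the labels name the human build GRCh38, but 32285 of 32285 gene identifiers in the deposited files are mouse Ensembl identifiers, so the counts were read as mouse counts. The annotation release is not given in the sources used here. The matrices listed 1745541 and 1854889 barcodes for the DiI-negative and DiI-positive steady-state libraries and 6794880 for each of the 3 later ones. Total UMIs were 112883648, 112920785, 52453186, 152805827 and 109506560 for the DiI-negative, DiI-positive steady-state, sensitized, day 1 and day 4 libraries.

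Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrially encoded UMIs were kept, which gave 7346, 5825, 2617, 7135 and 3699 barcodes. Scrublet, as contained in scanpy 1.11.5, was run per library at its default expected rate. It called 1, 74, 3, 0 and 2 doublets, that is 0.01%, 1.27%, 0.11%, 0.0% and 0.05%, so it has not worked in 4 of the 5 libraries and doublets remain there. After its calls were removed, 26542 cells were clustered together without integration across libraries. Clustering used log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 and seed 0. Clusters were named from 13 fixed marker lists of cell types, and neuron-like clusters were divided again and named from 8 fixed marker lists of neuron classes. A cluster took the list with the highest mean score, a log2 level over the mean of all clusters, if that score passed 0.5 and at least 3 of its markers were seen in at least 10% of the cells at 1.5-fold or more. A cluster with more markers of a rival class than of its own among its 10 leading genes was left unnamed. These details of the naming were settled after clusters had been seen. Neuron-like clusters with at least 3 markers of 1 non-neuronal type among those genes were set aside as mixed, and a cluster of 33 cells that scored as endothelial but was led by neuron class markers was left unnamed. Both rules were also set after the data were seen. Satellite-glia-like cells were summed in the same way for comparison.

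UMIs were summed over the neuron-like cells of each library, 78287306, 75749469, 34054959, 105169215 and 72997320, and expressed as CPM, that is scaled to the same total in each library. The log2 ratio of a pair of libraries has an exact conditional binomial interval, a level an exact Poisson interval and a share of cells an exact Clopper-Pearson interval, each at 95%. Counting error alone is covered. Where a library had 0 UMIs, the ratio was computed against a floor of 3 UMIs over the library. The libraries were grouped by their labels. The 4 main comparisons were DiI-positive over DiI-negative at steady state, sensitized over steady state, day 1 over sensitized and day 4 over sensitized, and 3 secondary ones were given as values. The last 2 main comparisons share the sensitized library, so no overlap between them was computed. With 1 library per group no test was run and cells were not used as replicates.

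The comparisons, the filters on cells, 16 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered itch and cytokine receptors, neuropeptides, nociceptor ion channels, neurotrophin receptors and lineage factors, axon injury and regeneration, immediate early genes, heat shock, interferon response, MHC class I, NFkB and inflammatory targets, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, synaptic and vesicle genes, inhibitory receptors and sex-linked genes. For each list the median log2 ratio of members with at least 10 UMIs over both libraries was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A named gene had at least 50 UMIs over both libraries, at least 50 CPM in 1 of them, and the same direction in at least 3 of every 4 neuron classes or clusters with at least 30 cells in both libraries and at least 20 UMIs of the gene. Mitochondrially encoded, ribosomal, haemoglobin, predicted, sex-linked and non-neuronal marker genes were excluded. Eligible genes were ranked by the interval bound nearest to a ratio of 1, and the 10 highest and 10 lowest were named. From each fixed list up to 4 members with the most extreme bound could be named, and Trpv1 was named in every library. Some genes that met this rule are not reported here, in the alternatives included, while the lists that hold them were kept whole. Sprr1a, Timp1 and other genes given within classes were taken from the genes so named. The genes of the plot of response genes, and Irf1 and Cxcl10 as exceptions on day 1, were picked after their values were seen, as were the genes given for the difference between steady-state and later libraries.

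Alternatives were 500 UMIs with 250 genes, 2000 UMIs, 5% and 20% mitochondrial UMIs, Scrublet calls kept, Leiden resolution 2.0, TMM factors, neuron classes weighted equally, neurons thinned to 1000 UMIs, free RNA subtracted and list members with at least 50 UMIs. Equal weights went to each named class and each unnamed cluster with at least 30 cells in both libraries. Unnamed clusters 6, 13, 20 and 26 thus counted as classes in the DiI comparison. Cluster 6 did so in sensitized over steady state and day 1 over sensitized. TRPM8-like cells were too few and were left out. TMM factors came from edgeR 4.0.16 and were 1.122, 1.052, 0.960, 0.975 and 0.905. Free RNA was taken from barcodes with at most 100 UMIs, and its share of the neuronal UMIs was estimated from 4 marker lists as 9.5%, 12.6%, 5.2%, 9.6% and 5.6%. Single markers gave values from 0.16% to 319%, so these shares are rough. After the data were seen, 4 alternatives were added. They were removal of the highest Scrublet scores, clustering without the genes of the state lists, keeping the mixed clusters, and giving each cluster its best class. The share of cells removed for high Scrublet scores was set at 0.8% per 1000 cells. Transcript length came from GENCODE M21, which was used for nothing else, and the genes were divided at 2517 and 4299 bases.

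The ratio and list procedures were tested on simulated data, drawn as Poisson counts from the pooled profile of each pair of libraries at their real depths. In each of the 4 main comparisons 100 of 100 genes changed 2-fold and 100 of 100 genes changed 1.5-fold were recovered with the right sign and an interval that excluded 0. The 95% intervals held the true ratio of 95.7%, 95.1%, 96.0% and 94.9% of unchanged genes in the 4 comparisons. Of 200 unchanged lists per comparison, 94%, 98.5%, 98% and 98% lay inside the random range, and a list raised by a median of 0.79 was found at 0.79. For changed genes the intervals held the true ratio of 89.0% to 98.0%. Genes and lists were drawn only from genes of at least 50 CPM in the pooled profile, so lower genes were not covered. These simulations carry no variation between animals or libraries. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Cell cycle, trajectories and ligand-receptor pairs were not analysed here, since 1 library per group gives no check on them.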

Results

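Sensory neurons of the dorsal root ganglion that supply the back skin were examined in mice at steady state and in contact hypersensitivity, an allergic skin inflammation evoked here by the hapten DNFB. The series design states that the neurons were labelled from the skin with the retrograde dye DiI and sorted by flow cytometry. There were 5 single-cell libraries, 1 for each of 5 groups, from mice of the TRPV1-ChR2-eYFP genotype. They were DiI-negative and DiI-positive cells at steady state, DiI-positive cells after sensitization, and DiI-positive cells at day 1 and at day 4 after challenge. In that order the libraries held 112883648, 112920785, 52453186, 152805827 and 109506560 UMIs, and 7345, 5751, 2614, 7135 and 3697 cells passed the filters. With 1 library per group no difference had a replicate check, and no p-value was computed. Intervals in brackets are exact, binomial for shares and ratios of counts, and cover counting error only.

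Neuron-like cells were 24.6% [23.6 to 25.6] of the DiI-negative library and 31.2% [29.96 to 32.37] of the DiI-positive library at steady state. They were 25.6% [23.9 to 27.3] of the sensitized library, 30.8% [29.8 to 31.9] on day 1 and 32.4% [30.9 to 34.0] on day 4. Satellite-glia-like cells, the glia that wrap sensory neuron bodies, were 3.01%, 15.6%, 59.5%, 40.9% and 55.3% of the 5 libraries in the same order. The DiI-negative library also held 21.9% myelinating-Schwann-like and 21.5% fibroblast-like cells, against 1.56% and 1.32% in its DiI-positive counterpart. Macrophage-like cells were 14.4% and endothelial-like cells 13.1% of the steady-state DiI-positive library. Unnamed clusters were 3.42%, 10.6%, 5.28%, 10.8% and 1.73% of cells. In 1 unnamed cluster led by Ctxn3 and Cd55, 261 of 333 cells came from the steady-state DiI-positive library. Clusters that joined neuronal transcripts with markers of another cell type were set aside by a threshold set after the data were seen. They were 1.21%, 7.42%, 0%, 0.15% and 0.05% of cells, and the 0 of 2614 cells in the sensitized library allows a share of up to 0.14%. The order of the steady-state pair was the other way with other minima for cells, 32.3% DiI-negative against 28.9% DiI-positive from 2000 UMIs and 26.1% against 22.6% from 500 UMIs. With at most 5% mitochondrial UMIs per cell the neuron-like shares were 56.0% after sensitization, 49.9% on day 1 and 79.7% on day 4, another order than above, and the shares of other cell types were not computed under alternatives. All these shares passed through the flow sort and through a minimum of 1000 UMIs per cell. Median UMIs per cell ran from 3319 in the DiI-negative library to 7879 on day 4.

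Neuron-like cells were sorted into classes by published markers of dorsal root ganglion neurons. NP1-like cells carry Mrgprd, NP2-like cells Mrgpra3, and NP3-like cells Sst and Nppb. PEP1-like cells carry peptides such as Tac1, C-LTMR-like cells Th, and TRPM8-like cells the cold channel gene Trpm8. Because these markers and Lpar3, Grik1 and Gal named the clusters, their values follow the classes and are not separate findings. Over the 5 libraries 1807, 1792, 669, 2199 and 1199 neuron-like cells were classed, with a median of 42187, 41906, 50414, 48475 and 62497 UMIs. NP1-like cells were 3.32% [2.54 to 4.25] of neuron-like cells in the DiI-negative library and 37.3% [35.1 to 39.6] in the DiI-positive library at steady state. Their share was 39.0% [35.3 to 42.8] after sensitization, 15.4% [13.9 to 17.0] on day 1 and 50.8% [47.9 to 53.7] on day 4. Among cells of at least 2000 UMIs it was 41.3% after sensitization, 11.2% on day 1 and 34.5% on day 4, so that day 4 then lay below the sensitized library. PEP1-like cells made up 31.2% [29.1 to 33.4], 17.1% [15.4 to 18.9], 18.4% [15.5 to 21.5], 29.4% [27.5 to 31.4] and 8.01% [6.53 to 9.69] in the same order. C-LTMR-like cells were 24.4%, 11.2%, 10.0%, 12.7% and 3.67%, and TRPM8-like cells 10.4%, 1.51%, 1.05%, 4.87% and 1.0%. The TRPM8-like share depended on the choices made and ran down to 3.81% in the DiI-negative library and to 1.95% on day 1.

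The classes did not consist of the same clusters in each library. Cluster 14 held most NP1-like cells of the DiI-negative library, cluster 5 was the largest NP1-like cluster of the steady-state DiI-positive library, and cluster 1 was the largest in the 3 later ones. NP1-like cluster 5 may be that library, since it took 303 of its 370 cells from there. NP1-like cluster 7, led by Pkib, Sdc1 and Gadd45a, took 222 of 308 cells from day 4. PEP1-like cluster 12, led by the inflammatory genes Ccl2, Timp1 and Ifitm1, took 199 of 252 cells from day 1, and PEP1-like cluster 28, led by Alkal2 and Timp1, took 87 of 104. The largest C-LTMR-like cluster was 3 at steady state and 11, led by the injury gene Fst, in the 3 later libraries. For NP3-like cells it was cluster 9 in the steady-state and sensitized libraries and 17 after challenge. Unnamed neuron clusters were 22.5%, 16.4%, 16.1%, 28.5% and 25.9% of neuron-like cells. Among them, cluster 4, led by the injury genes Sprr1a, Nts and Ecel1, was 0.33%, 1.12%, 4.33%, 5.59% and 17.4%. Clustered without the genes of the state lists, NP1-like shares were 3.37%, 37.8%, 39.1%, 15.1% and 48.7%, and PEP1-like shares 32.3%, 17.4%, 18.6%, 30.01% and 8.19%.

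**Figure D1:**
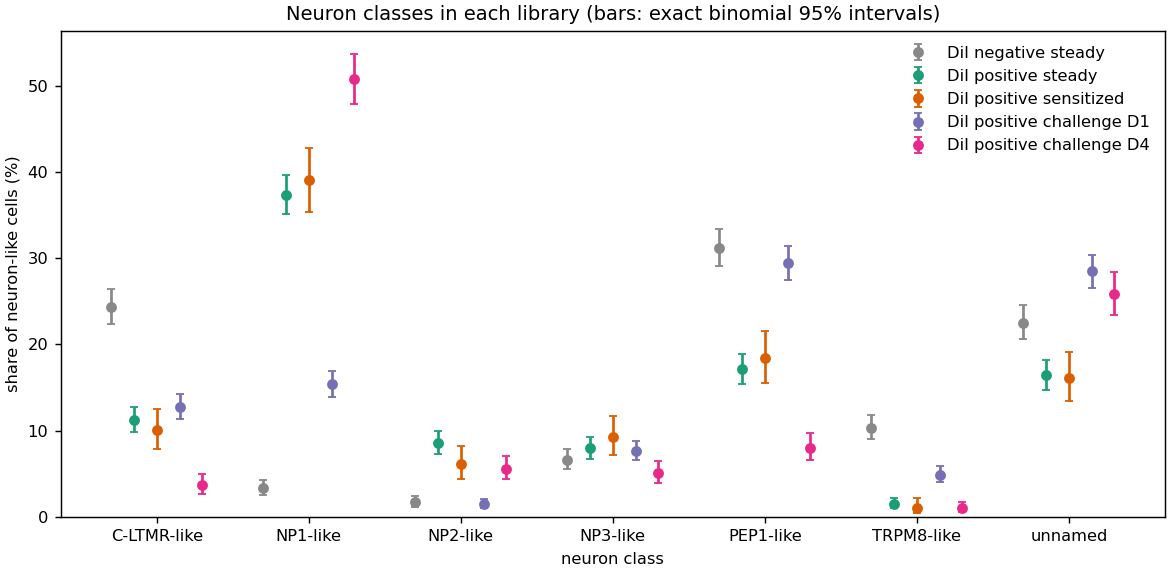
Share of each neuron class (x axis) among neuron-like cells (y axis, percent) in the 5 libraries, with exact 95% binomial intervals that cover counting error only. NP1-like cells were 3.32% of the DiI-negative and 37.3% of the DiI-positive library at steady state, and 39.0%, 15.4% and 50.8% after sensitization and on days 1 and 4.

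The comparison of DiI-positive with DiI-negative neurons asks what sets skin-supplying nociceptors apart at steady state. Markers of the NP1 and NP2 classes, which named the clusters, had median log2 ratios of 1.98 and 2.55. Ly86, which encodes a secreted partner of the Toll-like receptor homologue Cd180, was at 758 against 57.1 CPM (UMIs scaled to the same neuron-like total in each library), a log2 ratio of 3.73 [3.69 to 3.78]. The complement regulator Cd55 was at 551 against 118 CPM (2.22 [2.19 to 2.25]). Among genes with low ratios, Rprm was at 31.3 against 152 CPM (-2.28 [-2.34 to -2.21]) and the calcium sensor Hpca at 26.7 against 72.6 CPM (-1.45 [-1.52 to -1.37]).

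Further genes with high ratios in DiI-positive neurons were the kinase gene Prkcq (3.21), the complement inhibitor Serping1 (2.11), Klhl5 (2.08), the synaptic scaffold gene Anks1b (1.97) and the vesicle trafficking gene Rab27b (1.65). The class markers Lpar3 and Grik1 had ratios of 3.54 and 1.65. On the other side were Zcchc12 (-1.83), Ceacam10 (-1.80), the sodium pump regulator Fxyd6 (-1.65), Ly6h (-1.50), Rarres1 (-1.44) and Eid1 (-1.38), with the class markers Th (-1.56) and Gal (-1.48). Much of this went with the class mix. Equal weights here also counted unnamed clusters 6, 13, 20 and 26 as classes and left out TRPM8-like cells. Cluster 26 had a median of only 1603 UMIs. With each class weighted equally, Ly86 had a ratio of 1.30, Cd55 0.35, Prkcq 0.34 and Rprm -0.81, and the other named genes from 0.30 (Anks1b) to 0.89 (Lpar3) and from -0.22 (Hpca) to -0.78 (Ceacam10). Inside NP1-like cells Ly86 was at 1396 against 578 CPM, and inside PEP1-like cells at 82.7 against 36.5 CPM. Cd55 inside NP1-like cells was at 966 against 825 CPM, and Gal inside PEP1-like cells at 575 against 633 CPM.

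Receptor and peptide genes also differed. The itch receptor genes Mrgprd and Mrgpra3, both class markers, were at 58.9 against 7.88 CPM and at 39.9 against 7.31 CPM, while the cytokine receptor gene Tnfrsf1a was at 1.35 against 4.02 CPM. Among neurotrophin receptors, Gfra1 was at 37.5 against 10.0 CPM and Gfra3 at 90.6 against 203 CPM. The peptide genes Penk (3.21 against 46.3 CPM) and Cartpt (114 against 324 CPM) were low in DiI-positive neurons, whereas Npy had 73 UMIs against 0, a log2 ratio of at least 4.65 against a floor of 3 UMIs. Npy is also on the injury list, as is Sprr1a, at 24.7 against 0.345 CPM before any treatment. Of the 28 genes on that list, 4 were higher and 8 lower by at least 1.5-fold in DiI-positive neurons. Inhibitory receptor genes were low, with Adra2c at 7.23 against 18.8 CPM and Sstr2 at 12.3 against 27.0 CPM. The channel genes Kcnk18 (1.59) and P2rx3 (1.52) had ratios of -0.03 and -0.02 once classes were weighted equally. Trpv1, the gene named in the reporter genotype, was at 86.2 against 169 CPM, a ratio of -0.97 that was 0.19 with equal class weights.

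Of the 16 gene lists fixed before the data were examined, 8 had medians outside the 95% range of random lists matched on expression. Itch and cytokine receptors had a median log2 ratio of 0.23 (random range -0.24 to 0.04). Interferon response genes stood at 0.15 (-0.25 to 0.04), but at -0.11 after subtraction of free RNA. Neuropeptides had a median of -0.33 (-0.23 to 0.12), immediate early genes -0.33 (-0.29 to 0.08), heat shock genes -0.25 (-0.19 to 0.14) and mitochondrially encoded genes -0.61 (-0.19 to 0.19). Equal class weights changed these 4 medians to -0.06, -0.22, -0.15 and -0.30. The first 3 then lay inside the ranges given, but those were drawn over all neuron-like cells and none with equal weights. Inhibitory receptors had -0.53 (-0.28 to 0.09), or -0.01 with classes weighted equally, and synaptic genes -0.28 (-0.19 to 0.09), or 0.04. Inside their ranges were ion channels (-0.16), neurotrophin receptors and lineage factors (-0.04), injury genes (-0.14), MHC class I (-0.01), NFkB targets (-0.33), nuclear oxidative phosphorylation (-0.04), ribosomal proteins (-0.06) and sex-linked genes (-0.25). Inside NP1-like cells the itch list had a median of -0.06, against 0.42 in C-LTMR-like cells. Markers of other cell types in the neuron-like cells differed as well, with medians for endothelial ones of 1.85, macrophage 1.22, satellite glia 1.16, non-myelinating Schwann 0.52, mural -4.26, neutrophil -3.50, erythroid -3.49, fibroblast -2.08 and myelinating Schwann -1.76, each outside its range.

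The comparison of sensitized with steady-state DiI-positive neurons asks what sensitization alone left in the skin nociceptors. Of the 10 genes named here as high in the sensitized library, Atf3 and Fos were on the list of immediate early genes and Socs3 and Atf3 on that of injury genes. Socs3, an inhibitor of cytokine signalling, was at 97.8 against 22.5 CPM (2.12 [2.04 to 2.21]). Atf3 was at 290 against 71.3 CPM (2.02 [1.97 to 2.07]), Gadd45g at 462 against 156 CPM (1.57 [1.53 to 1.60]) and Fos at 258 against 104.0 CPM (1.31 [1.27 to 1.36]). Low ratios were found for the ATP synthase subunit gene Atp5k, at 333 against 976 CPM (-1.55 [-1.58 to -1.52]), and for the junctophilin gene Jph4, at 73.9 against 190 CPM (-1.36 [-1.42 to -1.30]).

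Other genes with high ratios were Spry2 (1.58), Frat2 (1.46), Bhlhe41 (1.35), Cebpb (1.29), Phlda1 (1.26) and the volume-regulated channel gene Lrrc8a (1.19). Those with low ratios were Lst1 (-1.47), Nudcd3 (-1.40), Polr2l (-1.34), Jph3 (-1.30), Pet100 (-1.24) and Dctn1 (-1.12), with the complex I genes Ndufb1-ps (-1.27) and Ndufa3 (-1.15). The fixed list of nuclear oxidative phosphorylation genes had a median of 0.01, with 0 of 24 genes lower by at least 1.5-fold. In free RNA the ratios were low as well, at -1.47 for Atp5k, -1.05 for Ndufb1-ps and -1.27 for Ndufa3, so they were not particular to neurons. Several classes showed the same direction. Socs3 had a ratio of 2.39 in NP1-like, 2.74 in NP3-like and 1.76 in PEP1-like cells. Atf3 was at 849 against 147 CPM in NP3-like cells and had a ratio of 0.60 in C-LTMR-like cells. Among channels, Hcn2 was at 8.52 against 21.3 CPM and Trpv1 at 46.5 against 86.2 CPM (-0.89, or -0.66 with equal class weights). Inside PEP1-like cells Trpv1 was at 146 against 202 CPM. Of the opioid and GABA receptor genes, Oprm1 was at 3.41 against 8.38 CPM and Gabbr1 at 138 against 215 CPM. The interleukin-31 receptor gene Il31ra was at 9.75 against 18.1 CPM and Jak1, a kinase under many cytokine receptors, at 202 against 339 CPM. The chemokine gene Ccl2 was at 91.1 against 30.2 CPM, the heat shock gene Dnajb1 at 138 against 67.5 CPM and Ngfr at 40.7 against 90.7 CPM. Injury genes included Gadd45a, at 101 against 45.2 CPM, and Sprr1a, at 98.5 against 24.7 CPM, which had a ratio of -0.21 with classes weighted equally.

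Immediate early genes had a median log2 ratio of 0.72, above the random range of -0.38 to 0.12, with 19 of 22 genes above 0. The list median was 0.53 in NP1-like, 1.22 in NP3-like, 0.73 in PEP1-like and 0.04 in C-LTMR-like cells. Injury genes, which share Atf3 with that list, had 0.29 (-0.24 to 0.17), or 0.03 with classes weighted equally, and mitochondrially encoded genes 0.30 (-0.22 to 0.29), or 0.27. Ion channels had a median of -0.49 (-0.34 to 0.07), synaptic genes -0.50 (-0.28 to 0.19), inhibitory receptors -0.50 (-0.42 to 0.13), itch and cytokine receptors -0.37 (-0.35 to 0.05), and neurotrophin receptors and lineage factors -0.34 (-0.32 to 0.19). With classes weighted equally these 5 medians were -0.37, -0.44, -0.34, -0.36 and -0.29. The inhibitory and neurotrophin medians then lay inside the ranges given, but no range was drawn with equal weights. The other 8 lists lay inside their ranges, among them interferon response genes (-0.32), MHC class I genes (-0.03) and NFkB targets (0.05), the last at 1.22 after subtraction of free RNA and 1.10 when neurons were thinned. Markers of other cell types in these neuron-like cells had medians of -3.37 (endothelial), -2.19 (macrophage), -1.37 (fibroblast), -1.22 (erythroid), -0.64 (myelinating Schwann) and 0.93 (T and NK cells), each outside its range. The median of 7465 expressed genes was itself -0.11, or 0.02 with TMM scaling. On both scalings the ion channel, synaptic, inhibitory, itch and neurotrophin lists kept negative medians and the immediate early list a positive one.

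The sensitized and steady-state libraries also differed in ways that the treatment does not name. The median ratio was 0.17 for genes with the shortest transcripts and -0.39 for those with the longest, and in satellite-glia-like cells it was 0.25 and -0.52. The same trend separated day 1 (0.19 and -0.44) and day 4 (0.10 and -0.44) from the steady state, but not the 3 later libraries from each other. No label gives a date or a batch. If the 2 steady-state libraries were processed apart from the 3 later ones, the design could not separate this from treatment. Against random lists matched on length as well, the neurotrophin list lay inside its range (-0.41 to 0.06) and immediate early genes lay above theirs (-0.29 to 0.16), but the interferon list, at -0.32, lay below its own (-0.24 to 0.14). The interferon median was 0.02 after subtraction of free RNA, inside that range, though no range was drawn for subtracted values. With TMM scaling it was -0.18, but TMM moves each gene alike, so the list's place among random lists stays the same.

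The comparison of day 1 after challenge with the sensitized library asks how skin nociceptors differ early in the allergic reaction. Of the 10 genes named here as high on day 1, Ifitm3 was on the interferon list and Gal on the injury and neuropeptide lists. Timp1, an inhibitor of matrix proteases, was at 382 against 11.7 CPM (5.03 [4.89 to 5.18]). The antiviral membrane protein genes Ifitm1 and Ifitm3 were at 63.3 against 11.8 CPM (2.42 [2.27 to 2.57]) and at 77.4 against 17.7 CPM (2.13 [2.01 to 2.25]). After subtraction of free RNA Ifitm1 had a ratio of 2.35, but too few counts of Ifitm3 were left for a ratio. Ifitm3 had a ratio of 1.98 in free RNA and was at 3017 against 1121 CPM in satellite-glia-like cells. Its value in neuron-like cells was thus not separated from RNA of other cells. The peptide gene Gal, a class marker, was at 879 against 222 CPM (1.99 [1.95 to 2.02]). Among low ratios, Rab27b was at 56.5 against 224 CPM (-1.99 [-2.04 to -1.94]) and the adhesion gene Cd24a at 809 against 2100.0 CPM (-1.38 [-1.39 to -1.36]).

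High ratios were also found for Kif22 (2.33), the protease inhibitor Serpinb1a (2.13), the calmodulin regulator Pcp4 (1.77), Fxyd5 (1.76), the ALK ligand gene Alkal2 (1.75) and Gpx3 (1.70). Low ratios, some of them of markers of the NP1 class, whose share differed, were found for Lpar3 at -2.06, Mrgprd -1.70, Klhl5 -1.60, Ctxn3 -1.50, Cd55 -1.46, Unc119 -1.40 and Grik1 -1.32. With classes weighted equally Timp1 had a ratio of 3.54, Serpinb1a 2.79, Alkal2 1.94, Kif22 1.89, Ifitm3 1.63 and Ifitm1 1.36. Gal had 0.89, Pcp4 0.76, Gpx3 0.74 and Fxyd5 0.34. On the low side Rab27b had -1.09 and Lpar3 -0.88, and the other genes with low ratios ran from -0.41 (Grik1) to -0.80 (Cd24a). Timp1 was at 911 against 39.4 CPM in PEP1-like, at 225 against 5.20 in NP3-like and at 39.2 against 0.438 in NP1-like cells. In unnamed cluster 6, which carried the glial transcripts Apoe and Fabp7, its ratio was -0.98. Gal was at 936 against 3.94 CPM in C-LTMR-like cells and at 1109 against 824 in PEP1-like cells. Interferon and antigen presentation genes included Irf7, at 15.7 against 5.14 CPM, and the immunoproteasome gene Psmb8, at 130.3 against 56.3 CPM. H2-K1 was at 174 against 99.0 CPM and Tap1 at 10.7 against 5.08 CPM, whereas Irf1 (-0.77) and Cxcl10 (-0.82) had negative ratios. The chemokine genes Ccl2, at 248 against 91.1 CPM, and Ccl7, at 33.6 against 10.4, had ratios of -0.14 and -0.24 with classes weighted equally. Among injury genes, Fst was at 32.7 against 2.79 CPM and Hspb1 at 1592 against 700.3 CPM. Early genes were lower, with Egr1 at 18.6 against 43.6 CPM and Fosb at 7.45 against 23.5 CPM. The itch receptor gene Mrgpra3 was at 3.57 against 23.5 CPM, and Trpv1 at 90.3 against 46.5 CPM, a ratio of 0.96 that was 0.18 with equal class weights.

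Interferon response genes had a median log2 ratio of 1.03, above the random range of -0.13 to 0.20, with 22 of 25 genes above 0. Markers of other cell types were also higher in these neuron-like cells, endothelial ones with a median of 2.16 (-0.34 to 0.72), macrophage ones 1.21 (-0.43 to 1.02), fibroblast ones 1.0 (-0.26 to 0.61) and erythroid ones 4.44 (-0.39 to 0.94). Their levels were low, with the endothelial gene Cldn5 at 0.789 against 0.176 CPM. Non-myelinating Schwann markers had a median of 0.51 (-0.31 to 0.34). Over the steady state, day 1 had -0.84 for endothelial, -1.09 for macrophage and -0.91 for fibroblast markers, against 3.18 for erythroid markers, 1.61 for T and NK cell markers and 0.51 for interferon genes. The interferon median over sensitized was 1.20 in NP1-like, 1.18 in NP2-like, 1.64 in NP3-like, 0.48 in PEP1-like and 1.06 in C-LTMR-like cells. MHC class I genes had a median of 0.85 (-0.21 to 0.27), with 11 of 11 genes above 0, and 0.42 with classes weighted equally. NFkB targets, which share Socs3 with the injury list, had 0.82 (-0.18 to 0.42) and neuropeptides 0.79 (-0.17 to 0.20), and each had 0.02 with classes weighted equally. Injury genes had 0.31 (-0.14 to 0.14), from 1.74 in C-LTMR-like to -0.23 in PEP1-like cells. Mitochondrially encoded genes had 0.27 (-0.24 to 0.21), nuclear oxidative phosphorylation genes 0.15 (-0.15 to 0.13) and immediate early genes -0.41 (-0.14 to 0.23). With classes weighted equally they had 0.15, 0.12 and -0.98. Against random lists matched on length as well, the mitochondrially encoded (-0.09 to 0.28) and oxidative phosphorylation genes (-0.07 to 0.19) lay inside their ranges. The other 8 lists lay inside their ranges, itch and cytokine receptors at -0.01 and ion channels at -0.11 among them. The median of 7323 expressed genes was -0.02. The sensitized library was the shallowest, with 34054959 UMIs in neuron-like cells against 105169215 on day 1, and it served both challenge comparisons.

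**Figure D2:**
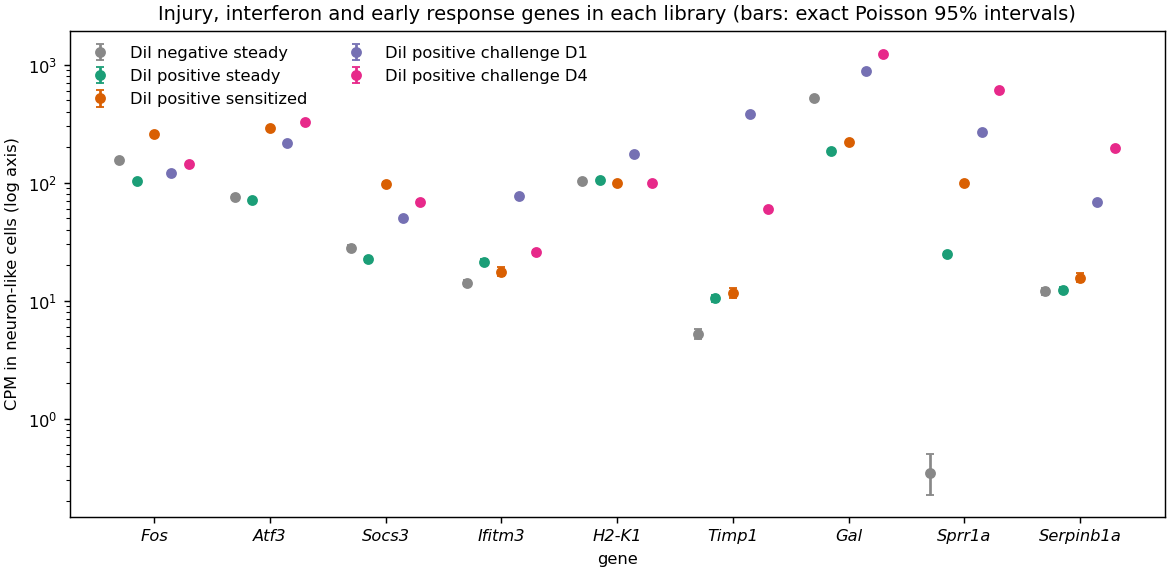
CPM of 9 genes (x axis) in neuron-like cells (log y axis) in the 5 libraries, with exact 95% Poisson intervals that cover counting error only; the genes were picked after their values were seen. Timp1 was at 11.7 CPM after sensitization, 382 on day 1 and 59.7 on day 4, while Serpinb1a was at 15.7, 68.7 and 197.

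The comparison of day 4 after challenge with the sensitized library asks which differences were present later in the reaction. Of the 10 genes named here as high on day 4, Sprr1a and Gal were on the injury list. Serpinb1a was at 197 against 15.7 CPM (3.65 [3.53 to 3.78]) and Sprr1a, which promotes neurite outgrowth, at 613 against 98.5 CPM (2.64 [2.59 to 2.69]). The peptide gene Gal was at 1241 against 222 CPM (2.49 [2.45 to 2.52]) and Timp1 at 59.7 against 11.7 CPM (2.36 [2.21 to 2.51]). Among low ratios, the NP3 marker Sst was at 14.4 against 66.5 CPM (-2.21 [-2.32 to -2.10]) and Car8 at 26.4 against 96.4 CPM (-1.87 [-1.95 to -1.79]).

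Other genes with high ratios were Fam210b (2.22), Kif22 (2.19), the kinase inhibitor gene Pkib (1.84), Alkal2 (1.67), the syndecan gene Sdc1 (1.54) and Nnat (1.52). Low ratios were found for the C-LTMR marker Th (-2.18) and for Wfdc2 (-2.0), Camk2n1 (-1.53), the mitochondrial kinase gene Ckmt1 (-1.51), Fxyd6 (-1.49), Nrsn1 (-1.39), Rarres1 (-1.39) and Etv1 (-1.35). With classes weighted equally Serpinb1a had a ratio of 3.65, Sprr1a 2.85, Timp1 3.41 and Gal 1.53. On the low side Sst had -1.58, Car8 -1.19, Th -0.46, Wfdc2 -0.63, Camk2n1 -0.95 and Ckmt1 -0.43. Fxyd6 had -0.39, Nrsn1 -0.58, Rarres1 -0.31 and Etv1 -0.92. Much of several low ratios thus went with the class mix, but less of that of Sst. Serpinb1a was at 73.7 against 3.63 CPM in NP1-like and at 77.9 against 22.3 CPM in PEP1-like cells. Gal was at 668 against 3.94 CPM in C-LTMR-like cells and at 1092 against 824 CPM in PEP1-like cells, and Sprr1a at 32.9 against 35.5 CPM in PEP1-like cells. The regeneration factor Sox11 was at 98.0 against 42.7 CPM over all neuron-like cells and at 67.7 against 35.1 CPM in NP1-like cells. Fst was at 29.9 against 2.79 CPM. Early genes were lower than after sensitization, with Fos at 143 against 258 CPM, Dusp1 at 53.7 against 116 CPM and Junb at 98.5 against 195 CPM. The acid-sensing channel gene Asic3 was at 2.40 against 9.46 CPM and Kcnq3, a potassium channel gene, at 7.49 against 2.35 CPM. Inhibitory receptors included Oprk1, at 0.466 against 2.32 CPM, and Sstr2, at 4.00 against 11.8 CPM. Among cytokine receptors, Il4ra was at 38.8 against 21.5 CPM, and the itch-related gene Htr1f was at 9.69 against 22.8 CPM. Trpv1 was at 49.4 against 46.5 CPM.

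Injury genes had a median log2 ratio of 0.41, above the random range of -0.13 to 0.05, with 22 of 28 genes above 0. The median was 0.65 in NP1-like, 0.33 in NP2-like, 0.22 in NP3-like, 1.14 in C-LTMR-like and -0.22 in PEP1-like cells. This list shares Gal, Npy, Nts and Vgf with the neuropeptide list, Hspb1 with the heat shock list, Stat3 with the itch list and Cacna2d1 with the ion channels. Interferon response genes had 0.25 (-0.22 to 0.03), with 0.26 in NP1-like, 0.61 in NP3-like and -0.09 in NP2-like cells. Immediate early genes had -0.42 (-0.22 to 0.07), itch and cytokine receptors -0.29 (-0.18 to 0.03), synaptic genes -0.28 (-0.14 to 0.06) and inhibitory receptors -0.50 (-0.22 to 0.07). These 4 medians were, at equal class weights, -0.72, -0.10, -0.13 and -0.15. The last 3 then lay inside the ranges given, but no range was drawn with equal weights. Neuropeptides had -0.34 (-0.15 to 0.08) and neurotrophin receptors and lineage factors -0.40 (-0.17 to 0.06), and each had 0.02 with classes weighted equally. The other 8 lists lay inside their ranges, among them MHC class I (-0.12, or 0.04 with classes weighted equally) and NFkB targets (0.05). Markers of other cell types in these neuron-like cells had medians of 3.32 (erythroid), 1.22 (neutrophil), 0.77 (macrophage), 0.53 (endothelial) and -0.44 (myelinating Schwann), each outside its range. The median of 7221 expressed genes was -0.05. C-LTMR-like cells numbered 67 in the sensitized library and 44 on day 4, and 5 classes had enough cells in both libraries. Cluster 4, with 29 cells after sensitization, had too few, so values with classes weighted equally leave it out in each comparison with the sensitized library.

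**Figure D3:**
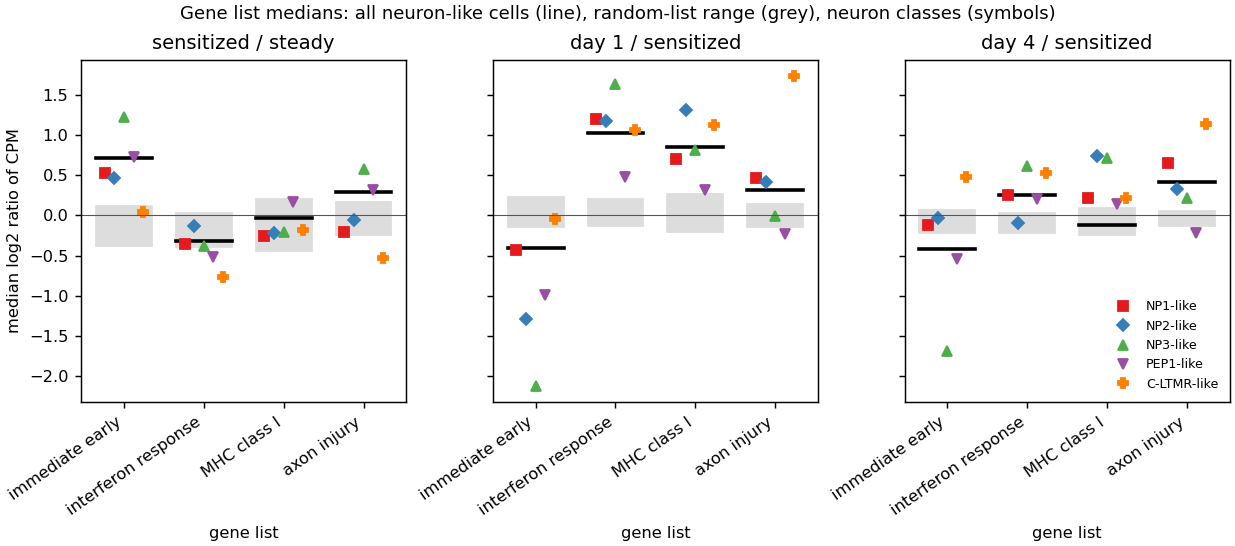
Median log2 ratio of CPM (y axis) of 4 gene lists (x axis) in sensitized over steady-state, day 1 over sensitized and day 4 over sensitized libraries, with symbols for neuron classes, black lines for all neuron-like cells and grey boxes for the 95% range of random lists. Interferon response genes on day 1 had medians of 0.48 in PEP1-like to 1.64 in NP3-like cells, and injury genes on day 4 ran from -0.22 in PEP1-like to 1.14 in C-LTMR-like cells.

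The secondary comparisons set the challenge days against each other and against the steady state. On day 4 over day 1, interferon response genes had a median log2 ratio of -0.74, MHC class I genes -0.89, neuropeptides -0.76 and inhibitory receptors -0.73, while injury genes had 0.19. On day 1 over steady state, interferon response genes had 0.51, MHC class I genes 0.97, injury genes 0.81 and immediate early genes 0.03. On day 4 over steady state, injury genes had 1.0, interferon response genes -0.15 and inhibitory receptors -1.0. Ratios over the steady state carry the length trend between the earlier and later libraries described above. The secondary comparisons were not run with classes weighted equally, so their medians were not separated from the class mix. That mix differed between the challenge days, with NP1-like cells at 15.4% on day 1 and 50.8% on day 4, and PEP1-like cells at 29.4% and 8.01%.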

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

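Of the tests given here, the one on transcript length, the one on dissociation behind the injury genes and the one within NP1-like cells were chosen only after the result was seen, and the bounds of the others were set with the medians over all neuron-like cells known. The values that stood out were differences of opposite sign between the challenge days, not under each alternative, and signals in satellite-glia-like cells, which the comparisons did not use. None of these differences was tested, because each group had 1 library.

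The share of NP1-like cells differed from the sensitized library by -23.64 percentage points on day 1 and by 11.78 on day 4. Among cells of at least 2000 UMIs the shares were 41.33% after sensitization, 11.22% on day 1 and 34.53% on day 4, both days below the sensitized library. For PEP1-like cells the differences were 11.03 and -10.38 points. The neuropeptide list had a median log2 ratio of 0.79 on day 1 and -0.34 on day 4. Both days share the sensitized library. Of the neuropeptides, Gal, Tac1, Adcyap1, Sst, Nppb and Nts are also class markers, and the list medians were 0.02 on each day with classes weighted equally.

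In satellite-glia-like cells the sensitized over steady-state medians were 0.76 for immediate early genes and 0.76 for NFkB targets, lists that share no gene. Between the 2 untreated steady-state libraries, DiI-positive over DiI-negative, the immediate early median in them was -2.84, and day 4 over steady state had 0.58 for immediate early genes and 0.95 for NFkB targets. Neuronal (-2.56), endothelial (-2.19) and fibroblast (-0.99) markers were lower in the sensitized glia, which also lay in other clusters, with 527 of 898 steady-state cells in cluster 7 and 579 and 406 of 1555 sensitized cells in cluster 0 and in cluster 8, led by early genes such as Arc and Fos. On day 1 over sensitized, interferon response genes had 1.06, injury genes 0.82 and MHC class I genes 0.79 in these cells. Neuronal markers (1.01), neuropeptides (2.14), endothelial markers (1.15) and mural markers (1.54) were higher in them as well, so the day 1 values of the glia were not separated from RNA of other cells. There were 221, 898, 1555, 2916 and 2045 such cells in the 5 libraries. On day 1 the acute-phase gene Serpina3n was at 295 against 30.8 CPM in them, and sensitized over steady state Dnajb1 had a log2 ratio of 3.20, Arc 3.33 and Socs3 2.04.

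The first pattern weighed was the immediate early median of 0.72 in sensitized over steady-state neurons. A different class mix is argued against by a median of 0.60 with classes weighted equally. Transcript length is argued against by an excess of 0.56 over random lists matched on length. After subtraction of free RNA the median was 1.58. That subtraction took 12.6% from the steady-state and 5.2% from the sensitized library, rough shares whose difference can itself raise the ratio. The 1.58 therefore cannot decide on free RNA. Handling or dissociation of the whole suspension predicted a rise in the glia too, and their median of 0.76 goes with it. Between glia of the untreated libraries the median was -2.84, DiI-positive over DiI-negative. Of the DiI-negative ones 149 of 221 lay in cluster 8, led by early genes, against 91 of 898 DiI-positive ones. Satellite glia (0.93) and myelinating Schwann markers (-0.94) differed between them too. The -2.84 therefore does not separate handling from which cells took the name. Over the steady state the medians were 0.03 on day 1 and 0.07 on day 4 in neurons, and -0.19 and 0.58 in the glia. The 0.07 lay above its random range (-0.51 to 0.06), but inside the range matched on length as well (-0.42 to 0.12). These values leave open free RNA, a batch difference between the 2 steady-state and the 3 later libraries, handling of single libraries, and a response of neurons and glia to sensitization.

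The second pattern was the interferon response median of 1.03 on day 1 over sensitized. Free RNA is argued against by a median of 0.90 after its subtraction, and a different class mix by 1.06 with classes weighted equally. RNA from attached cells of other types stays open as a source of part of it, because endothelial markers had 2.16 and erythroid markers 4.44 in the same neurons. On day 1 over the steady state endothelial markers had -0.84, erythroid markers 3.18 and interferon genes 0.51, which does not settle it. A difference between the libraries in processing, or a response to the challenge in the ganglion in which the glial median of 1.06 could share, stays open too with 1 library per group.

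The last pattern was the injury median of 0.41 on day 4 over sensitized. A stress response to dissociation cannot be told apart from an effect of the challenge, since the immediate early median was -0.42 over a sensitized library itself high in these genes, and 0.07 over the steady state. With classes weighted equally the injury median was 0.26, between the bounds set and without unnamed cluster 4, which is led by injury genes and held 29 sensitized and 209 day 4 cells, so a partial effect of the class mix cannot be told apart from a change within classes over all neurons. Inside NP1-like cells the median was 0.65, which argues against the mix of classes there, although cluster 7, mostly of day 4, belongs to that class. Free RNA is argued against in the neurons by a median of 0.41 after its subtraction as well, although no bound was set for this value. An origin in the whole suspension or in RNA of attached cells stays open, as the glia had an injury median of 0.42 with neuronal markers at 0.37. Damage to axons in inflamed skin, by the dye labelling or by the sort could also give such a pattern and was not tested.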

How the results depend on the processing

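Removal of the highest Scrublet scores, keeping mixed clusters, clustering without state genes and naming each cluster were tests chosen only after the data were seen. Where a value moved, the cause was not tested. No paired analysis was possible because each group had 1 library and nothing links animals across groups. Of the gene ratios under these alternatives, 1810 stayed within the counting interval, 889 moved without a change of sign and 29 changed sign, and for list medians outside the leading ones these counts were 391, 185 and 4. For shares of cells other than the leading ones, 190 stayed within the interval and 105 moved. With Scrublet calls kept, 0 of 310 gene ratios moved. Of these 310, free RNA subtraction gave values for 300 (not for Ifitm3 on day 1), equal class weights for 303 and thinning for 265, since the others had no counts left or too few cells. With each cluster named, PEP1-like shares were 51.7%, 28.8%, 28.9%, 50.2% and 14.5%, and NP3-like shares 6.92%, 9.04%, 13.6%, 13.2% and 22.5%. The TRPM8-like share of the DiI-negative library was 4.98% with Scrublet calls kept and 4.61% without state genes, against 10.4%, and that of day 1 was 2.96% and 2.54%, against 4.87%. From 500 or 2000 UMIs no cluster was named NP2-like.

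The immediate early median in sensitized over steady state was 0.72 and ran from 0.56 to 1.58. Interferon medians ran from 0.90 to 1.07 on day 1 and from 0.20 to 0.47 on day 4, injury medians from 0.18 to 0.37 on day 1 and from 0.26 to 0.50 on day 4, and the itch median of DiI-positive over DiI-negative from 0.09 to 0.42. These kept their sign under each alternative run. The NP1-like share ran from 2.44% to 4.37% in the DiI-negative library, from 26.6% to 42.0% in the steady-state DiI-positive library, from 11.2% to 17.6% on day 1 and from 34.5% to 53.3% on day 4.

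With TMM factors B2m in DiI-positive over DiI-negative had a ratio of 0.02 instead of -0.07 and H2-K1 in sensitized over steady state 0.04 instead of -0.09. Medians were 0.32 for itch receptors (DiI), 0.85 for immediate early genes (sensitized), and 0.50 for injury and 0.33 for interferon genes (day 4).

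At 20% mitochondrial UMIs the neuron-like shares were 22.39%, 29.16%, 23.46%, 26.38% and 27.08% from the DiI-negative library to day 4, and the steady-state DiI-positive NP1-like share was 27.80%. At 5% they were 28.43%, 39.32%, 56.03%, 49.93% and 79.71%, with NP1-like shares of 4.37% (DiI-negative), 42.04% (steady-state DiI-positive) and 17.58% (day 1), and the itch median was 0.09. From 2000 UMIs the neuron-like shares were 32.29% and 28.92% in the steady-state libraries, and NP1-like shares 2.44%, 32.60%, 41.33% (sensitized), 11.22% (day 1) and 34.53% (day 4), so day 4 over sensitized took the other direction than at 1000 UMIs. The steady-state neuron-like shares also changed order. From 500 UMIs and 250 genes neuron-like shares were 26.11%, 22.58%, 22.60%, 29.63% and 30.12%, with the steady-state pair again in the other order. At resolution 2.0 the steady-state DiI-positive library had 32.74% neuron-like and 33.99% NP1-like cells.

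After subtraction of free RNA Il33 had a DiI ratio of 1.92 instead of -1.77, and in sensitized over steady state H2-K1 had 0.28 instead of -0.09 and Rsad2 0.38 instead of -1.0. The medians were -0.11 for interferon genes (DiI), 1.58 for immediate early genes (sensitized) and 0.90 for interferon genes (day 1). Without the highest Scrublet scores Penk on day 4 had 0.41 instead of -2.42, and the steady-state DiI-positive library 29.94% neuron-like and 26.61% NP1-like cells. With mixed clusters kept the immediate early median was 0.56, neuron-like shares were 25.81% and 38.58% in the steady-state libraries, and the second had 30.15% NP1-like cells.

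With classes weighted equally the DiI ratios of H2-T23 (0.18), Oprl1 (0.12), Ddx3y (0.15), Sv2a (0.21) and Trpv1 (0.19) became positive and those of Mrgprd (-0.22), Kcnk18 (-0.03) and P2rx3 (-0.02) negative, and the synaptic median was 0.04. Sprr1a in sensitized over steady state had -0.21. On day 1 Ccl7 (-0.24), Ccl2 (-0.14), Kdm5d (-0.02) and Sv2a (-0.11) became negative. On day 4 Ccl2 (0.04) and Slc17a8 (0.10) became positive, as did neuropeptides (0.02) and neurotrophin receptors (0.02). The leading medians were 0.60 for immediate early genes (sensitized), 0.18 for injury genes (day 1), and 0.26 for injury and 0.47 for interferon genes (day 4).

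With neurons thinned to 1000 UMIs B2m had 0.20 and Tapbp -0.02 in the DiI comparison, H2-K1 0.09 in sensitized over steady state, and Eif2s3y 0.18 on day 1. On day 4 Tap1 had 0.16, mt-Nd5 -0.02, Uqcrc1 -0.03 and Sv2b 0.57, each of the other sign than unthinned. Medians were 0.42 for itch receptors (unthinned 0.23), 0.92 for immediate early genes (0.72), 0.91 for interferon genes on day 1 (1.03) and 0.39 on day 4 (0.25). Thinning left 1000 UMIs of a median of 41906 to 62497, so low genes had few counts.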

Other observations

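All values here were looked for only after the data were seen. Several genes, of which Atf3, Socs3, Nudcd3, Jph4, Jph3 and Dctn1 are named in the report, differed between the 2 steady-state and the 3 later libraries. In neuron-like cells Lars2 was at 28.2, 24.5, 8.40, 8.72 and 7.54 CPM in the DiI-negative, DiI-positive steady-state, sensitized, day 1 and day 4 libraries. AY036118, a ribosomal-RNA-like transcript, was at 11.6, 9.61, 1.12, 2.33 and 0.343 CPM, and Gm42418 at 325, 186, 65.1, 126 and 41.4 CPM. Jph4 was at 162, 190, 73.9, 87.3 and 67.7 CPM, Jph3 at 45.6, 55.5, 22.5, 24.8 and 20.9 CPM, and Dctn1 at 217, 256, 118, 133 and 109 CPM. Named as high after sensitization, Atf3 was at 76.3, 71.3, 290, 215 and 324.5 CPM. Socs3 was at 28.2, 22.5, 97.8, 50.3 and 68.8 CPM. Fos did not divide the libraries in this way, at 157, 104, 258, 121 and 143 CPM. Nudcd3 had log2 ratios over the DiI-positive steady state of -1.40, -1.33 and -1.68 in the sensitized, day 1 and day 4 libraries. The steady-state matrices also listed fewer barcodes than the later ones, 1745541 and 1854889 against 6794880.

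Interferon response genes in sensitized over steady-state neurons had a median of -0.32. Matched on transcript length as well as expression, the random range was -0.24 to 0.14, so the median lay below it. The median was 0.02 after subtraction of free RNA, for which no range was drawn. TMM scaling gave -0.18 but moves each gene alike, so it does not change the list's place against its random range. Ion channels, at -0.49, lay just below theirs (-0.47 to -0.16), and synaptic genes, at -0.50, below -0.38 to 0.06.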
